A study of Arabidopsis thaliana with 6 samples.

How the data were processed

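Polyadenylated RNA was sequenced from self-pollinated siliques of *Arabidopsis thaliana* collected 1 to 5 days after pollination, in 3 libraries of the *eml1 eml3* double mutant and 3 of the wild type (WT). The labels give each library's genotype and number. They do not say that libraries came from separate plants or harvests, so the p-values measure the spread between these samples, which may be technical. The accessions of WT and mutant are not given in the sources used here.

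Trim Galore, STAR 2.5.2a, SAMtools, featureCounts, Subread and DESeq2 are named, with no role or order, in the submitters' processing notes. The genome build, annotation release, strand setting and treatment of multi-mapping reads are not given in the sources used here, so no coordinates are printed. The library protocol in the labels does not describe a step that marks the strand. The TAIR10.1 reference table gave symbols, biotypes, neighbour order, overlaps and copies. It held 37051 of the 37336 gene IDs, and 285 did not match.

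The signal analysed was gene counts divided by 1 size factor per library, made by the authors with DESeq2, per the file headers and the submitters' processing notes. Every value was a whole multiple of its library's smallest value above 0 to within 1e-06, in 100% of values, so whole reads were recovered. The recovered totals were 38196040, 31503946 and 27046107 reads in WT replicates 1, 2 and 3, and 39246167, 31569842 and 26771227 in mutant replicates 1, 2 and 3. Among genes with 1 to 20 reads in a library, even counts made up 69.3% to 73.9%. Among genes with 101 to 1000 reads they made up 49.6% to 52.4%. Counts that come in pairs, as when both mates of a fragment are counted, would give such an excess of even numbers at low counts. Intervals and floors below treat each read as independent and cover counting error only, so they are narrower than fragments would give. The second deposited table holds the authors' log2 fold changes with standard errors, per the file headers. It also holds the authors' p-values and adjusted p-values, per the file headers, with the adjusted p-value blank for 12829 genes.

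Genes with a mean normalized value of at least 10 over the 6 libraries were tested, 21751 in all. The test was limma 3.58.1 in R 4.3.3 with a variance trend on log2(value + 1), mutant minus WT, with genotype as the only term. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. For a gene with 0 reads in a group, the fold is a lower bound against 3 reads over the group. For a gene with 1 to 3 reads it is a ratio with a 95% exact binomial counting interval.

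Gene lists, 27 in all, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. One list is every gene whose reference symbol starts with SAUR. Members past the threshold were counted over all genes and adjusted over the list alone. The 24 lists with at least 5 tested members were compared with other genes by limma's camera with a preset correlation of 0.01, with an estimated correlation beside it. The form with an estimated correlation also rests on the few degrees of freedom left by 6 libraries. A list that does not pass there is therefore not shown to fail through correlation. Fry tested the same lists against no change, without reference to other genes. The auxin lists were chosen knowing that the study names auxin genes from these samples, so they are not independent evidence of direction.

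The named genes were EML1 to EML4, and the 10 largest rises and 10 largest falls among genes past the threshold. The latter had to carry a symbol, have a mean of at least 50 in the higher group, and have all mutant libraries on one side of all WT libraries. From each list the rule took up to 4 members past the threshold with the smallest adjusted p, or, where none passed, the 2 with the smallest p. Other genes named were chosen after their values were seen, to spell out small counts or family members.

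Transcripts of named genes and list members were aligned to all reference transcripts with BLAST 2.17.0. A near-identical copy has at least 95% identity over at least 150 bases, and genes with one, or with an overlapping gene, are reported as uncertain. Families were built from the annotation's product names, keeping those with at least 10 tested members, and tested by one-sided Fisher's exact test in SciPy 1.17.1 against 20936 tested genes with an informative product name.

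Alternatives were other pseudocounts (0.5 and 5), filters, a robust variance prior, other scalings, a replicate block, leaving out each library, and edgeR 4.0.16 or DESeq2 1.42.0 on the recovered reads. Leaving out both libraries numbered 3 was added after seeing the data. On simulated counts for the same design, limma over 21693 genes recovered 43% of 100 genes changed 2-fold and 81% of 100 genes changed 4-fold, with 14 false calls among 138. In that test edgeR made 20 false calls among 146, and DESeq2 35 among 176. Few genes were changed in it, and its counts did not come in pairs. These rates therefore need not hold for the real libraries.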

Results

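The series compared silique RNA of the *eml1 eml3* double mutant with that of WT, 3 libraries each, from self-pollinated siliques 1 to 5 days after pollination. Siliques hold the fruit wall and the developing seeds, so each value is a mixture of fruit, seed coat, endosperm and embryo. The EML proteins carry an ENT domain and Tudor-like domains, and the series title calls them histone readers that prevent seed development in unfertilized ovules. Recovered depth was 26771227 to 39246167 reads per library. Normalized read counts are given as mean ± SD with n = 3 libraries per genotype.

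EML3 (AT5G13020) was 12.5-fold lower in the mutant. Its normalized count was 2367 ± 310 (SD, n = 3) in WT and 187 ± 12.6 (SD, n = 3) in the mutant, a log2 change of -3.65 ± 0.15 (SE, limma adjusted p = 2.24e-06). It ranged from 173 to 198 in the mutant libraries and from 2129 to 2718 in the WT libraries. EML1 (AT3G12140) stood at 1144 ± 83.7 (SD, n = 3) in the mutant and 1281 ± 88.0 (SD, n = 3) in WT, which did not pass the test (limma adjusted p = 0.499). A count over the whole gene does not show whether the *eml1* allele leaves a partial transcript, so it does not check that allele. The other family members, EML2 (AT5G06780; limma adjusted p = 0.962) and EML4 (AT2G44440; limma adjusted p = 0.345), did not pass either.

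**Figure D1:**
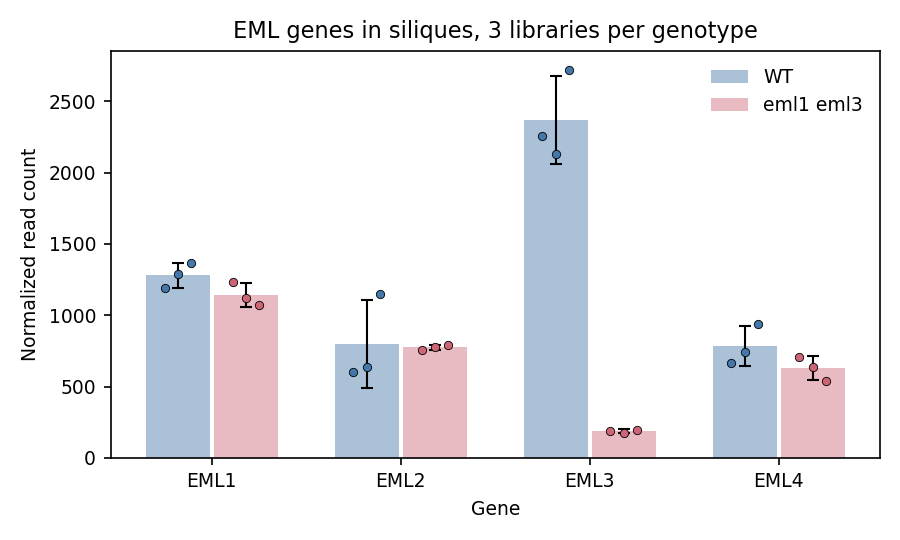
Normalized read counts of the 4 EML genes, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. EML3 falls from 2367 in WT to 187 in the mutant, and the EML1 means are 1281 and 1144.

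Between the genotypes 1476 of 21751 tested genes passed the threshold in limma, 802 higher and 674 lower in the mutant. Of these, 768 differed at least 2-fold, 362 of them higher and 406 lower. Rescaling the libraries to one total gave 1478 genes but a split of 615 higher and 863 lower, so the balance of directions depends on the scaling. The count changed with each library left out. It was 818, 634 and 893 without WT replicates 1, 2 and 3, and 664, 571 and 2613 without mutant replicates 1, 2 and 3.

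Among the 10 largest rises, CSA1 (AT5G17880), a TIR-NBS-LRR disease resistance gene, had 0 reads in WT and 261 ± 36.1 (SD, n = 3) normalized counts in the mutant, at least 269.8-fold higher. DAR4 (AT5G17890), the nearest protein-coding gene in the reference, rose from 4.29 to 881. TGG2 (AT5G25980), a myrosinase that breaks down glucosinolates, rose from 405 ± 7.72 to 32179 ± 2942 (SD, n = 3), 79.0-fold. AOP2 (AT4G03060), which modifies glucosinolate side chains and is annotated as a transcribed pseudogene in the reference, rose from 1.12 to 125. The expansin EXPA23 (AT5G39280) rose 67.7-fold to 5174 ± 228 (SD, n = 3). XTH17 (AT1G65310), a xyloglucan-modifying enzyme, had 0 WT reads and was at least 90.4-fold higher, at 152, 89.1 and 21.4 in mutant replicates 1, 2 and 3. With 3 WT reads, the glutamate receptor gene GLR2.1 (AT5G27100) had a ratio of 168 (95% counting interval 57.2 to 818). With 2 WT reads, MSRB4 (AT4G04810) had a ratio of 131 (35.8 to 1085). FAR8 (AT3G44560), a fatty acyl reductase, and the retroposon-derived SADHU6-1 (AT3G02515) complete the 10 rises, at 89.9 and 1140 in the mutant against 1.31 and 10.4 in WT. XTH17 and FAR8 lost their calls without mutant replicate 1 or without mutant replicate 2.

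Among the largest falls was ESM1 (AT3G14210), which influences what glucosinolates are broken down to, from 3974 ± 67.8 to 29.8 ± 18.7 (SD, n = 3), 146-fold. AOX1C (AT3G27620), an alternative oxidase, had 0 reads in the mutant and was at least 66.9-fold lower. The retroposon-derived SADHU5-2 (AT5G27927) fell from 368 to 5.82 and SADHU3-1 (AT3G44042) from 1694 to 29.6. SK9 (AT3G21850) fell from 513 to 7.32 and the receptor-like gene RLP42 (AT3G25020) from 211 to 3.48. ABCB16 (AT3G28360) fell from 122 to 4.55, ACP5 (AT5G27200) from 561 to 39.6 and HISN6B (AT1G71920) from 62.1 to 2.19. SOT7 (AT1G28170) fell from 109 to 13.4 with a limma adjusted p of 0.048, while its adjusted p in the authors' deposited table was 0.533. It lost its call under most alternatives, among them edgeR with its filter, DESeq2 and leaving out any one library except mutant replicate 3. In edgeR without the filter SOT7 kept its call. AOX1C and ACP5 lost theirs without WT replicate 1 or 2, ACP5 also with a robust variance prior and with the replicate block in edgeR, and HISN6B without any one WT library. Single libraries weighed on several low means. In mutant replicates 1, 2 and 3 ACP5 was at 3.25, 12.2 and 103, SOT7 at 0, 0 and 40.3, ESM1 at 13.8, 25.3 and 50.4, SK9 at 4.06, 4.05 and 13.9 and SADHU5-2 at 4.87, 0 and 12.6. EXPA23, HISN6B, RLP42 and SADHU6-1 have near-identical copies, and GLR2.1 and ACP5 overlap another gene, so their values are uncertain. In all, 158 called genes were at least 16-fold apart. Away from EML1 and EML3, 31.7% of such genes had another within 5 tested genes, against a median of 8.45% for draws from other called genes. The draws were not matched for biotype or near-identical copies. Each of the largest rises and falls named above was at least 16-fold apart. Strain background, taken up under the first pattern below, was not excluded for them, so their changes cannot be assigned to the mutations. Background was not tested for the 1318 called genes less than 16-fold apart. With the accessions not given, it stays open for them too.

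Among auxin-induced genes more were called higher than lower in the mutant. Of 31 tested Aux/IAA and GH3 genes, 9 rose and 1 fell, and 16 passed when adjusted over the list alone, 14 higher and 2 lower. IAA17 (AT1G04250) rose 3.65-fold from 546 ± 96.5 to 1980 ± 230 (SD, n = 3; limma adjusted p = 0.000103). IAA1 (AT4G14560) rose 4.77-fold, IAA19 (AT3G15540) 6.24-fold and GH3.3 (AT2G23170), an auxin-conjugating enzyme, 1.89-fold. The member that fell was GH3.2, from 702 to 221. The list was higher than other genes in camera (adjusted p = 0.00184), but not with an estimated correlation (adjusted p = 0.345), where no list passed. This list was chosen knowing that the study names auxin genes from these samples, so it is not independent evidence. Higher calls numbered 8, 5 and 7 without WT replicates 1, 2 and 3, and 5, 5 and 11 without mutant replicates 1, 2 and 3.

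Of 15 tested genes with a SAUR symbol, 5 rose and 0 fell, and 12 passed when adjusted over the list alone, all higher. SAUR26 (AT3G03850) rose 3.44-fold, SAUR27 (AT3G03840) 3.55-fold and SAUR20 (AT5G18020) 2.25-fold. SAUR63 was the fifth, and it has a near-identical copy. The gene carrying the symbol SAUR21 (AT5G01830) rose 2.76-fold, but the annotation calls its product an ARM repeat protein, not a small auxin-induced protein. The list was higher in camera (adjusted p = 2.98e-07), but not with an estimated correlation (adjusted p = 0.345), where no list passed. It is an auxin list too and not independent evidence. The list's direction was the same under each scaling tried. SAUR20 and SAUR27 lost their calls with the replicate block in edgeR, and SAUR20 also with that block in limma. Higher calls numbered 5, 3 and 4 without WT replicates 1, 2 and 3, and 3, 2 and 6 without mutant replicates 1, 2 and 3.

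**Figure D2:**
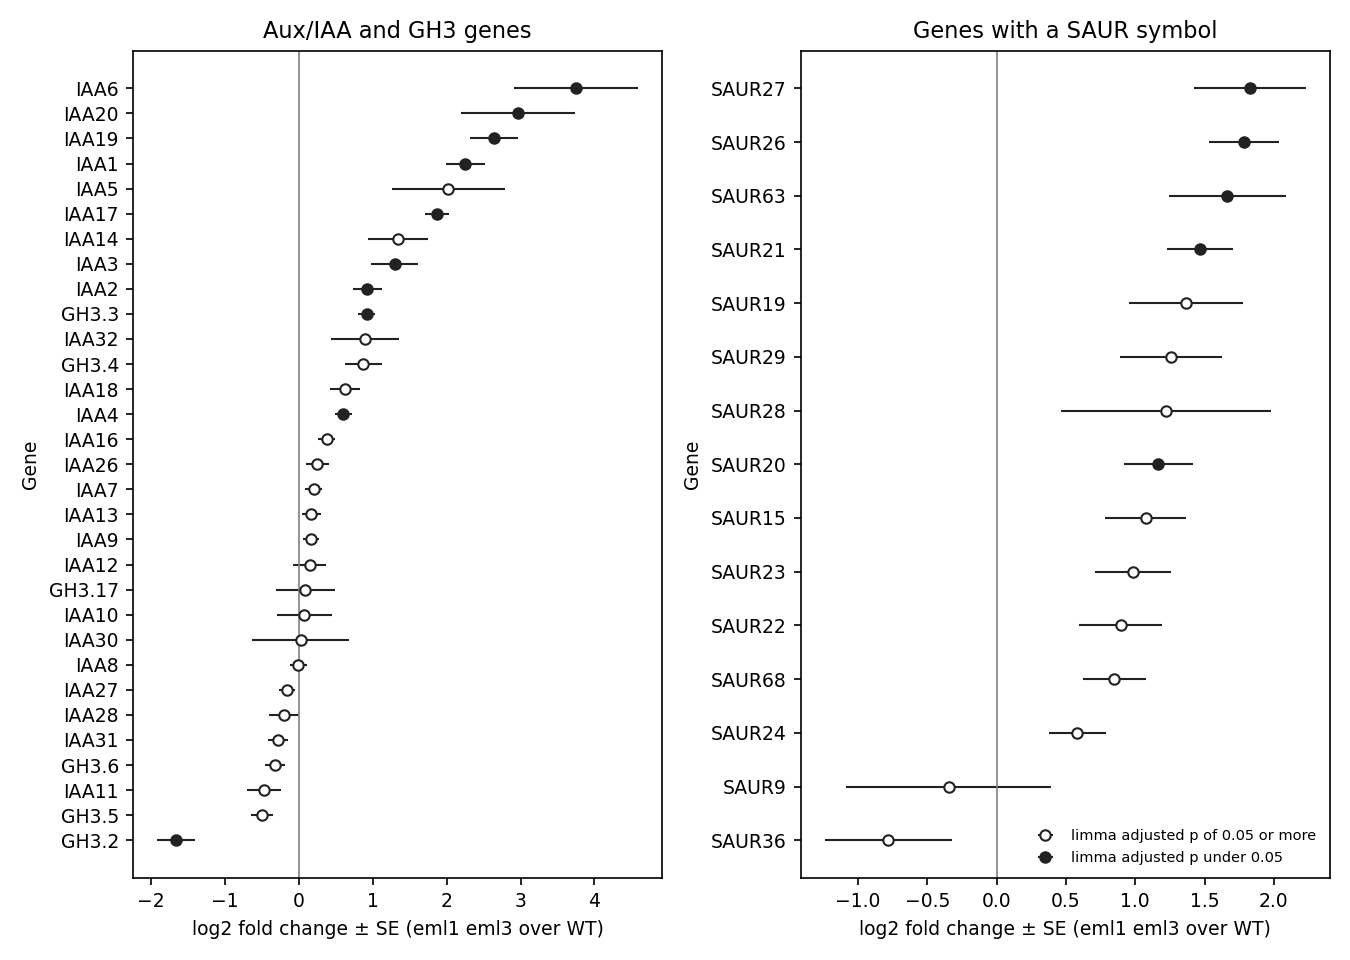
Log2 fold change (mutant over WT) with its SE for the tested Aux/IAA and GH3 genes and the genes with a SAUR symbol; filled points passed the limma threshold. Of the first group 9 genes rose and 1 fell, and of the second 5 rose.

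Among 25 tested auxin transport genes 4 rose and 0 fell, and 6 passed when adjusted over the list alone, all higher. PID (AT2G34650), a kinase that directs auxin efflux carriers, rose 2.17-fold from 450 ± 43.5 to 975 ± 93.0 (SD, n = 3; limma adjusted p = 0.00192). The influx carriers LAX2 (AT2G21050) and LAX3 (AT1G77690) rose 2.05-fold and 1.59-fold, and ABCB19 (AT3G28860) 1.53-fold, the last not past the threshold after rescaling to one total or quantile normalization. With the replicate block in limma or edgeR neither LAX2 nor ABCB19 passed. Calls numbered 1, 2 and 2 without WT replicates 1, 2 and 3, and 1, 1 and 4 without mutant replicates 1, 2 and 3. Camera did not call the list (adjusted p = 0.261, or 0.951 with an estimated correlation), except with edgeR and no filter (adjusted p = 0.0448). Of 21 auxin response factors and receptors, the receptor gene AFB1 (AT4G03190) rose 1.75-fold and ARF11 (AT2G46530) fell 2.22-fold, and 2 passed when adjusted over the list alone. AFB1 lost its call under all 3 other scalings, with a pseudocount of 0.5, with no filter and in edgeR with its filter, with or without the replicate block, and both lost theirs without any one library except mutant replicate 3. Of 8 auxin synthesis genes 0 passed in limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 called by edgeR or DESeq2. YUC3 (AT1G04610) stood at 161 in the mutant and 93.9 in WT, and TAR2 (AT4G24670) at 667 and 918. These lists are not independent evidence either.

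Lists of chromatin and seed genes held few calls with all 6 libraries. In limma 0 of 12 Polycomb genes, 0 of 5 H3K36 methylation genes, 0 of 18 endosperm genes, 0 of 17 genes imprinted in endosperm, 0 of 9 seed coat epidermis and integument genes and 0 of 15 seed storage genes passed, over all genes or when adjusted over the list alone. At an unadjusted p under 0.05 the counts were 0, 0, 1, 4, 2 and 1 in that order. Across these lists edgeR with its filter called 0 genes, and DESeq2, which gave p-values for 4 of the storage genes, called HDG9, GL2 and OLEO4. Camera called the storage list higher on that edgeR fit (adjusted p = 0.00901, 10 genes). Without the filter edgeR called 10 of 16 storage genes higher (camera adjusted p = 9.83e-09) and 1 imprinted gene lower. In the main limma fit camera did not call the storage list (adjusted p = 0.416, or 0.977 with an estimated correlation of 0.934). No correlation was estimated with edgeR. The female gametophyte list had 1 tested member, AGL80 (AT5G48670), which did not pass. MEA (AT1G02580) stood at 161 in the mutant and 98.2 in WT, LHP1 (AT5G17690) at 526 and 653, AGL28 (AT1G01530) at 111 and 52.7, and SUC5 (AT1G71890) at 1763 and 2036. SDG26 (AT1G76710) stood at 558 and 635, and MRG2 (AT1G02740) at 308 and 349. HDG9 (AT5G17320) stood at 619 and 411 and HDG3 (AT2G32370) at 1056 (1853 in mutant replicate 3) and 2004, GL2 (AT1G79840) at 2153 and 3062, and BEL1 (AT5G41410) at 1104 and 1510. Of 19 embryo genes 1 fell, WRI1 (AT3G54320), a regulator of seed oil synthesis, from 1153 ± 146 to 633 ± 262 (SD, n = 3), and 2 passed when adjusted over the list alone. WRI1 lost its call under quantile normalization, with a pseudocount of 0.5, with no filter, with the replicate block, in edgeR with its filter and without any one library except mutant replicate 3. Of 19 flavonoid genes FLS1 (AT5G08640), flavonol synthase, rose 2.31-fold and TT7 (AT5G07990) fell 1.39-fold, and 2 passed when adjusted over the list alone. TT7 lost its call with no filter in limma, with the replicate block in limma or edgeR, without WT replicate 1 or 2 and without mutant replicate 1 or 2.

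Mutant replicate 3 stood apart in these seed genes, and also over all tested genes. Its log2 values correlated at 0.930 and 0.931 with mutant replicates 1 and 2, which correlated at 0.979 with each other. WT replicate 2 and mutant replicate 1 correlated at 0.930. The cruciferin gene CRU1 was at 19059 there and at 16.2 to 35.3 in the other 5 libraries, and all 15 storage genes were highest in that library, among them CRU2 (AT1G03880) and OLEO4 (AT3G27660). The maturation regulators LEC1, FUS3, ABI3, L1L and WRI1 were lower in mutant replicates 1 and 2 than in every WT library, and higher in mutant replicate 3 than in both. EML3 in that library was 198. Without mutant replicate 3, camera called 5 lists in place of 3, adding the embryo and the storage lists, both lower (adjusted p = 0.0324 each). With an estimated correlation these calls were lost (adjusted p = 0.563 and 0.827). The median log2 change of the storage list was 1.62 with all libraries and -0.89 without that one. Limma then called 5 embryo, 2 storage, 2 endosperm, 3 seed coat epidermis and integument genes and 1 imprinted gene, all lower.

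**Figure D3:**
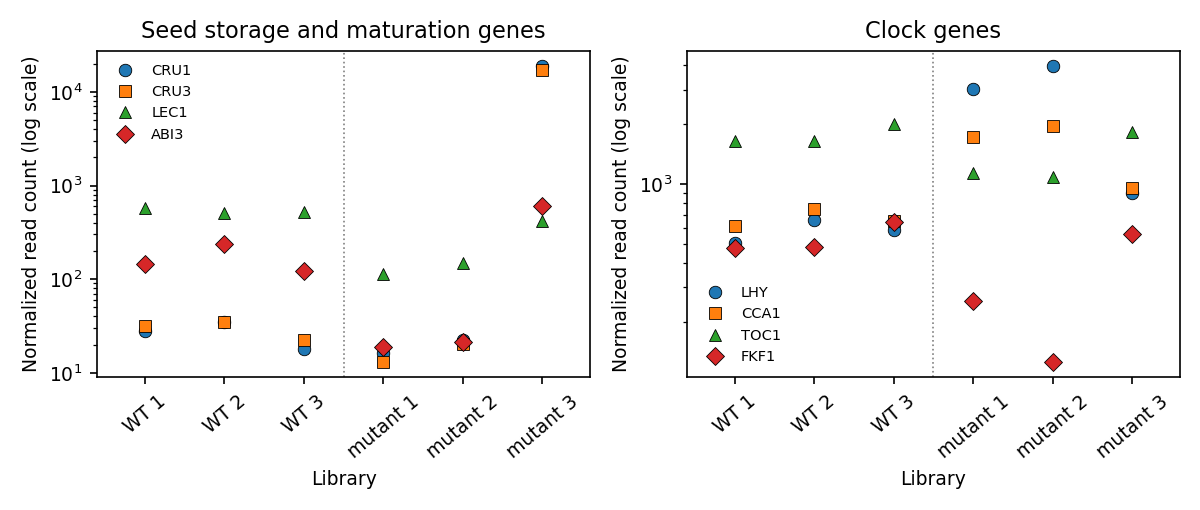
Normalized read counts per library on a log axis for 4 seed genes and 4 clock genes. CRU1 is at 19059 in mutant replicate 3, and LHY is at 3039 and 3970 in mutant replicates 1 and 2 and at 905 in mutant replicate 3.

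Single fruit and flower genes changed. Of 10 silique wall genes 1 fell, SHP1 (AT3G58780), which patterns the valve margin, 1.45-fold, and 2 passed when adjusted over the list alone. Of 3 other flower organ genes AP3 (AT3G54340) fell 1.80-fold from 3310 ± 652 to 1821 ± 133 (SD, n = 3), and 3 passed when adjusted over the list alone, all lower. Of 6 pollen genes PPME1 (AT1G69940) fell from 1480 ± 1066 to 377 ± 140 (SD, n = 3) and SUC1 (AT1G71880), a sucrose carrier, rose 1.73-fold, and 5 passed when adjusted over the list alone, 1 higher and 4 lower. PPME1 was at 2710 in WT replicate 3 and at 875 and 854 in the other WT libraries. SUC1 lost its call with the replicate block in limma or edgeR, without WT replicate 1 or 2 and without mutant replicate 1 or 2. PPME1 lost its call with a robust variance prior, with the replicate block in edgeR and without mutant replicate 2. With the block limma called 3 pollen genes lower. Camera called the pollen list lower with edgeR and no filter (adjusted p = 0.0046) and with edgeR and the block (adjusted p = 0.0422). It did not in the main fit (adjusted p = 0.261, or 0.951 with an estimated correlation of 0.754). Of 8 flowering time genes MAF2 (AT5G65050) fell 1.41-fold, and 3 passed when adjusted over the list alone, all lower. SHP1 and MAF2 lost their calls without any one library except mutant replicate 3 and with the replicate block in edgeR, and MAF2 also with that block in limma. Camera called the flowering list lower (adjusted p = 0.0227), which was lost with an estimated correlation (adjusted p = 0.721). It was also lost without WT replicate 1 (adjusted p = 0.0665) and without mutant replicate 1 (adjusted p = 0.0532), with a minimum mean of 50 (adjusted p = 0.0985) and with DESeq2 (adjusted p = 0.0734), and the lowest over the alternatives was 0.0099. Of 14 photosynthesis genes 0 passed in limma, edgeR or DESeq2 and 1 had an unadjusted limma p under 0.05, with RBCS1B (AT5G38430) at 40321 in the mutant and 31628 in WT and RBCS3B (AT5G38410) at 327557 and 248242.

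The clock and defence lists and the hormone lists other than auxin held at most 3 calls each in limma. Of 12 gibberellin genes 3 rose and 0 fell, over all genes and over the list alone: GA3OX1 (AT1G15550), a synthesis enzyme, 2.34-fold, and the DELLA genes RGL1 (AT1G66350) and GAI (AT1G14920) 1.49-fold and 1.48-fold. The DELLA proteins restrain gibberellin responses. Of 13 clock genes CCA1 (AT2G46830) rose 2.22-fold and LHY (AT1G01060) 3.82-fold, PRR7 (AT5G02810) fell 1.54-fold, and 4 passed when adjusted over the list alone. LHY was at 505 to 661 in WT, at 3039 and 3970 in mutant replicates 1 and 2 and at 905 in mutant replicate 3. Of 18 salicylic acid defence genes CBP60G (AT5G26920) rose 8.53-fold and PR2 (AT3G57260) 2.83-fold, and 5 passed when adjusted over the list alone, 3 higher and 2 lower. Rescaling to one total ended the calls of GAI and PR2, and the replicate block in limma or edgeR those of PR2 and CBP60G. PR2 also lost its call with no filter in limma, and LHY with a robust variance prior. Without WT replicates 1, 2 and 3 the salicylic acid list held 0, 1 and 2 calls, and without mutant replicates 1, 2 and 3 it held 0, 0 and 3. In that order the gibberellin list held 2, 1, 2, 2, 0 and 3 higher calls, with 1 lower without mutant replicate 3. The clock list held 1, 0, 0, 0 and 0 calls without the first 5 of these libraries, and 3 higher and 5 lower without mutant replicate 3. Fry, which tests a list against no change, called gibberellin higher (adjusted p = 0.0329), which camera did not (adjusted p = 0.28, and 0.911 with an estimated correlation), and both Aux/IAA with GH3 and SAUR higher (adjusted p = 0.0113 and 0.01). Of 22 cell division, 6 heat shock, 6 abscisic acid and cold, and 10 cytokinin genes 0 passed in limma, over all genes or when adjusted over each list alone. At an unadjusted p under 0.05 the counts were 4, 0, 1 and 1 in that order, and edgeR with its filter called 0. Without the filter edgeR called 1 cell division gene higher. Camera called the cell division list lower without WT replicate 1 (adjusted p = 0.0418), but not in the main fit (adjusted p = 0.261, or 0.951 with an estimated correlation). DESeq2 called only PCNA2, CDKB1;2 and ARR9. Fry called heat shock lower (adjusted p = 0.0478), which camera did not (adjusted p = 0.374). CDKB1;2 (AT2G38620) stood at 68.4 in the mutant and 16.5 in WT, PCNA2 (AT2G29570) at 759 and 508, HSP70B (AT1G16030) at 168 and 262, and HSP17.6A (AT5G12030) at 10.5 and 34.8 (77.8 in WT replicate 3). CBF3 (AT4G25480) stood at 13.4 and 50.8, RAB18 (AT5G66400) at 356 and 262, ARR9 (AT3G57040) at 269 and 433, and CKX2 (AT2G19500) at 933 and 1271. AFB1, SHP1, LHP1, SDG26, GL2, CDKB1;2, PCNA2, CBF3, RAB18, ARR9 and CKX2 overlap another gene, and PPME1 and RBCS3B have a near-identical copy, so their values are uncertain.

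The authors' deposited table held 2364 genes with an adjusted p under 0.05, 1256 higher and 1108 lower in the mutant. It shared 1459 of the 1476 limma calls, all in the same direction, on the same libraries. Of the 905 genes called only there, 844 had an unadjusted limma p under 0.05 and 58 were not tested by limma.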

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

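EML3 was past the threshold and EML1 was not under every alternative. With edgeR 1403 genes passed, and with DESeq2 2397 did (1275 higher, 1122 lower). A threshold of 0.01 left 526, and a fold of at least 2 left 768. Leaving out one library gave 571 to 2613 genes, 319 to 1157 higher and 249 to 1456 lower, with fewer samples. Leaving out both libraries numbered 3, added after seeing the data, gave 2991 (1400 higher, 1591 lower). The cause of these shifts was not tested. Fewer samples alone do not account for them. The count rose to 2613 without mutant replicate 3 and to 2991 without both libraries numbered 3, but fell without any other single library. Lists called by camera numbered 3, with 2 to 5 when one library was left out, 5 without both libraries numbered 3, 6 with edgeR and no filter and 0 with an estimated correlation. Without both libraries numbered 3, camera's adjusted p for the SAUR list went from 2.14e-05 to 0.469 at an estimated correlation of -0.035. That correlation was under the preset 0.01, so correlation does not account for that loss. Fry, a test against no change, called 4 lists, and 12 for changes in either direction. Of the genes in the authors' deposited table, 1475 passed at 0.01 and 1162 passed with a fold of at least 2. Of 51 named genes past the threshold, none changed sign under any alternative. In each of them all mutant libraries lay on one side of all WT libraries. Leaving out a library or changing the pseudocount, filter or variance prior could therefore not change a sign. Leaving out mutant replicate 2 ended 24 of the 51 calls, and DESeq2 ended 1. Depth limits genes of a few reads, for which only bounds or wide ratios can be given.

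The shared replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0788, -0.00199 and -0.169 across genes. With the numbers as a replicate block limma called 1203 genes and edgeR 1009, 438 of the latter lower. In these deviations no library correlated best with its own number in the other genotype.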

Other observations

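All families, all tests of patterns below except the count of other splits, and the genes named here were chosen after the data were seen. Of 294 product families, each tested in both directions (588 tests), 7 passed. Expansins, which loosen cell walls, held 11 higher of 20 tested genes (14.9-fold over background, adjusted p = 1.21e-08). The 11 include EXPA23, whose value is uncertain. EXPA1 rose from 2395 ± 124 to 8321 ± 1148 (SD, n = 3), EXPA10 3.54-fold and EXPA5 2.56-fold, and 11 passed each time one library was left out. Pectin lyase-like genes held 13 higher of 73 (adjusted p = 0.000482) and also 7 lower. SAUR-like genes by product held 12 higher of 56 (adjusted p = 0.000223) and 1 lower. SAUR20, SAUR26, SAUR27 and SAUR63 are among these 12, so the family counts again calls of the list of SAUR symbols. It is not separate evidence on auxin.

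GDSL lipase-like genes held 11 higher of 61 (adjusted p = 0.00189) and 2 lower, and acyltransferases of the HXXXD type 8 of 42 (adjusted p = 0.0129) and 1 lower. Among the latter were CER2, a cuticular wax gene, which rose 2.64-fold, and DCF, which rose 2.04-fold. ESM1, one of the largest falls, has a GDSL lipase-like product name in another spelling and was not counted in the GDSL family. On the lower side were inhibitors of invertase and pectin methylesterase, 9 of 53 (adjusted p = 0.00313) with 3 higher, and serine carboxypeptidase-like genes, 6 of 35 (adjusted p = 0.0477) with 4 higher. A family that differs from the inhibitors only in the wording of its product name held 5 higher of 30 (Fisher's exact adjusted p = 0.173). Whether its members are inhibitors was not checked. With 9 lower and 3 higher, the family of inhibitors itself did not move in one direction. Pollen genes without SUC1 summed to 4681 to 8469 in the mutant and 9258 to 24252 in WT, and a link to the inhibitors was not tested. Counts in the 6 families past the threshold other than expansins moved with single libraries. Without mutant replicate 1, pectin lyase-like genes held 6 higher, SAUR-like 6, GDSL 5 and HXXXD 4. Without mutant replicate 2 these held 7, 5, 7 and 4, and the families on the lower side held 0 and 1. Without WT replicates 1, 2 and 3 the inhibitors on the lower side held 2, 2 and 3 lower genes, and the carboxypeptidase-like genes 2 each time. Lower pectin lyase-like genes numbered 2, 3 and 2 there, and 7, 0 and 5 without mutant replicates 1, 2 and 3. Without mutant replicate 3 GDSL lipase-like genes held 7 lower, and those inhibitors 14. Tandem members are not independent of each other, so these p-values are smaller than independent genes would give.

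The first pattern was 158 genes at least 16-fold apart, 88 higher and 70 lower, among them 27 of 294 tested pseudogenes (9.18%) and 108 of 20864 protein-coding genes (0.518%). They lay unevenly along the chromosomes. In consecutive windows of 100 tested genes, chromosome 4 held 5, 5, 8 and 7 of its 31. Chromosome 3 held 5, 8, 8, 11 and 3 of its 59, and chromosome 5 held 5, 4, 6, 4 and 2 of its 36. The windows with EML1 and EML3 held 0 each, and no window outside these runs held more than 5. Genes on chromosomes without EML1 or EML3 cannot be linked to these alleles. Strain background carried along with the alleles is therefore argued against for the 63 genes there, by position alone. These were 39.9% of the 158, against 56.7% of tested genes, so the pattern was more frequent on the chromosomes of EML1 and EML3. Linked background stays open for the other 95. They made up 0.8% of the 2000 tested genes around EML1 and EML3 and 1.08% elsewhere on the same chromosomes (Fisher's exact p = 0.316, two-sided). Background in unlinked segments may account for part. Of the 63 genes on the other chromosomes, 27.0% had another within 5 tested genes. This was more than in any of 1000 draws from other called genes there (at most 19.0%). The draws were not matched for biotype or near-identical copies, so the excess alone does not show such segments. An effect of the mutations on neighbouring genes would cluster too, and stays open. Reads shared with a near-identical copy cannot be told apart for the 24.7% (39 genes) that have one; the others have no such copy.

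The second pattern was the storage transcripts of mutant replicate 3, with a summed count of 73016 over 15 genes against 648 to 1929 in the other libraries. A mislabelled WT library is argued against by EML3, at 9.29% of the lowest WT library. Ripe seeds are argued against by EM1 and EM6, abundant late in ripening, at 0% of CRU1. Older seeds in that library may be the source, since 5 of 5 maturation regulators were higher there than in both other mutant libraries. WT libraries had similar LEC1 (509 to 572) without such storage counts, and a difference in seed growth between mutant plants was not tested.

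The third pattern was the clock. The median log2 change was 1.05 for 4 morning genes and -0.35 for 7 evening genes, but CCA1 and LHY had drawn attention to it. The morning genes were CCA1, LHY, RVE8 and PRR9. The evening genes were TOC1, PRR5, GI, LUX, ELF4, FKF1 and BOA. PRR7, which fell 1.54-fold, and ELF3 were placed in neither set. Without CCA1 and LHY the difference of medians was 0.952 (exact permutation of phases over 36 assignments, p = 0.139, two-sided), with 2 morning genes left. Of these, PRR9 has a near-identical copy, so its value is uncertain. Harvest at different times of day therefore stays open, as does an effect of the genotype on the clock, which predicts the same difference of medians. Mean log2 of morning minus evening genes was 1.16 and 1.72 in mutant replicates 1 and 2, but -0.68 in mutant replicate 3, within the WT range of -0.76 to -0.31. The shift was therefore not shared by all mutant libraries.

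The real grouping called 1476 genes in limma, and the highest of the other 9 splits of the 6 libraries called 0, so that 1 of 10 splits, the real one, reached that count. The other splits had 88 to 1783 genes at an unadjusted p under 0.05, against 4684 for the real grouping. With 10 splits the share cannot go under 0.1. Each of the other 9 splits put both genotypes in both groups, so the genotype difference added to the spread within groups and lowered the calls. These splits therefore cannot show how many calls would arise without a genotype difference.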
